A study of Gallus gallus with 6 samples.

How the data were processed

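The series held 6 Affymetrix chicken arrays, 3 of bursal cells cultured on DF-1 monolayers with the vector and 3 on monolayers expressing SCA2, with the group and replicate number taken from the sample titles. The deposited values are one intensity per probe set and array on a linear scale, and per the submitters' processing notes they were made with RMA, whose usual steps are background correction, quantile normalization and a robust summary of the probes of a set. The version and settings of RMA are not given in the sources used here. RMA values are usually on a log2 scale, and these were not: they ran from 4.28 to 20715, so their log2 was taken before any test. Because RMA makes the overall distribution of the arrays alike, a shift common to all genes cannot be seen in these values, and a change in the abundance of one group of transcripts is measured relative to the rest.

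Of 38535 probe sets, 96 controls of the array were left out of the tests and 38439 were kept with no filter on dim ones. The calls given for control probe sets come from a separate limma fit of all 38535, with adjustment over all of them. Genes were named through the platform annotation, with symbols updated by gene identifier, which gave 27168 probe sets with 1 symbol, 177 with several and 11094 with none. No gene was named from a probe set with several symbols. No detection calls were used here. As a mark of background, the 95th percentile of 689 probe sets named after sequence records in place of chicken transcript clusters was taken, a log2 intensity of 4.92. A test of probe sets of avian viruses was planned, and since the annotation used here does not mark them it was not run as such.

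All computations used R 4.3.3 and limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A linear model with 1 term for the monolayer was fitted to each probe set over the 6 arrays with lmFit and eBayes at their defaults, and p-values were adjusted by the Benjamini-Hochberg method over the 38439 probe sets, with a threshold of 0.05. Log2 changes are SCA2 minus control, and standard errors are the moderated ones. The titles call the replicates biological, and the protocol describes triplicate cultures without saying that each came from its own birds, so p-values measure only the spread between these arrays, part of which may be technical. The array number limits precision, and 3 against 3 arrays cannot give an exact permutation p below 0.1.

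The 25 gene lists were tested with limma's camera on the moderated statistics of 1 probe set per gene, that of the highest mean over all arrays (13009 genes), with a preset correlation between genes of 0.01, Benjamini-Hochberg adjustment over the lists and at least 5 measured members. Camera compares a list with all other genes. Camera with a correlation estimated for each list and fry, which tests each list alone, were run beside it. Genes were named by a rule: LY6E, then the 12 raised and the 12 lowered genes of largest log2 change among called probe sets with 1 symbol and no overlap between groups, and up to 4 called members of each list with the smallest p. Other members of a list that are named, such as those that moved against their list, were chosen after their values were seen. The gene lists, the comparisons of the report, this rule and the other settings listed below were fixed before the data were examined. Cyclic loess normalization, the estimated correlation for the lists of other cell types taken alone, the 35 gene families, and the tests of cell mixture and of a reporter probe set were chosen after seeing the data. The rule for reading the COL1A1 percentile was made stricter after its value was known, since COL1A1 was bright on the control arrays as well.

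The alternatives were the replicate number as a block, a second quantile normalization, centring on the array median, filters at the median and the lower quartile of probe set means, a variance trend with a robust fit, array weights, stricter thresholds, an unmoderated test, other ways to join the probe sets of a gene and leaving out each array in turn. The procedure was tested on simulated arrays with 38439 probe sets of which 200 were changed. It recovered 76% of changes of log2 size 1 and 95% of those of size 2, made 8 calls among the unchanged probe sets, and called the 1 simulated list that was moved by -0.5 and 0 others. The simulated probe sets varied independently of each other. The simulation therefore does not test list calls where genes move together or where many probe sets change. No genome positions are given, since array probe sets were not placed on a genome here. The labels give no batch, and no scan dates were used here, so a batch that followed the groups cannot be told apart from them.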

Results

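RNA was measured in cells of the bursa of Fabricius, the organ in which chicken B cells develop, after overnight culture on a monolayer of DF-1 cells, a chicken embryo fibroblast line. The bursae came from 3-week-old line 0 chickens. In one group the monolayer expressed a tagged stem cell antigen 2 (SCA2, the product of LY6E, a small membrane protein held by a lipid anchor). In the control group it carried the vector. In each culture 2000000 bursal cells were plated and kept at 37 °C in medium with 4% serum, then washed off the adherent monolayer, and 10 µg of total RNA was labelled for an Affymetrix chicken array. There were 3 control arrays and 3 SCA2 arrays, each with 38439 probe sets after the array's own control probe sets were left out. Deposited intensities ran from 4.28 to 20715, and the median per array lay between 51.2 and 53.1. The number of arrays limits the precision of every value.

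The arrays separated by group. Across probe sets, log2 intensities correlated with r between 0.99 and 0.995 among the control arrays, between 0.995 and 0.997 among the SCA2 arrays and between 0.962 and 0.98 across groups. The first principal component held 77.6% of the variance and placed the control arrays between -67.5 and -41.9 and the SCA2 arrays between 45.1 and 64.6. The second component held 10.3% and placed control 1 at -35.7 and control 2 at 28.6. The median standard deviation of a probe set was 0.13 (log2) among the control arrays and 0.10 among the SCA2 arrays.

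The comparison asked how the RNA of cells recovered from the SCA2 monolayer differed from that of cells recovered from the vector monolayer. Whether the harvest also held monolayer RNA is left open below, so the changes cannot be assigned to bursal cells alone. Genes of B cell identity, T cells, macrophages and antigen presentation were lower on the SCA2 arrays, together with targets of NF-kB and cytokines. Many genes of the fibroblast and extracellular matrix list, of cholesterol synthesis, of protein folding in the endoplasmic reticulum and of mitosis were higher. These are calls of limma's camera with a preset correlation, and 0 of the 25 lists were called with an estimated correlation. The largest rise was that of WIF1, a secreted inhibitor of Wnt ligands, from 3.79 ± 0.29 to 11.48 ± 0.06 (log2 intensity, mean ± SD, n = 3 each). The largest fall was that of PTGS2, the inducible cyclooxygenase that starts prostaglandin synthesis, from 11.52 ± 0.83 to 8.32 ± 1.19. In limma with Benjamini-Hochberg adjustment, 13557 of the 38439 probe sets (35.3%) passed an adjusted p of 0.05, of which 6992 were higher and 6565 lower with SCA2. They stood for 3942 named genes with a higher and 3422 with a lower probe set among 13009 named genes tested, and 221 of these genes had probe sets in both directions. A change of at least 2-fold was found for 1667 of the higher and 1325 of the lower probe sets, and of at least 4-fold for 175 and 77. The groups did not overlap in 48.9% of all probe sets, where chance gives 10%.

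Beside WIF1, the largest rises included ABLIM1, which binds actin (log2 change 4.73, SE 0.10, 26.5-fold; limma, Benjamini-Hochberg adjusted p = 4.7e-06), and MXRA5, a matrix remodelling protein (4.45, SE 0.29, 21.9-fold; adjusted p = 5.8e-05). WIF1 itself changed by 7.69 (SE 0.14, 206-fold; limma, Benjamini-Hochberg adjusted p = 4.5e-06). The dynein heavy chain gene DNAH5L rose by 4.01 and the glycosyltransferase gene GLT8D2 by 3.51. NALCN, a sodium leak channel, rose by 3.40, GABRA2, a subunit of the GABA-A receptor, by 3.33 and CAMK2A, a calcium/calmodulin-dependent kinase, by 3.29. IRX1, a homeobox transcription factor, changed by 3.30, SGCD, the delta subunit of the sarcoglycan complex, by 3.21, VSTM4 by 3.21 and N4BP2L1 by 3.13. Their adjusted p-values in limma with Benjamini-Hochberg adjustment lay between 7.6e-06 and 6.3e-05. Some of the raised genes had other probe sets that moved the other way, of which 0 were called. A rise was seen in 7 of 9 probe sets of ABLIM1 and in 3 of 5 each of DNAH5L and NALCN. It was seen in 3 of 4 for SGCD and in 2 of 3 for N4BP2L1. The control means of WIF1, MXRA5, DNAH5L, GLT8D2, GABRA2 and N4BP2L1 lay below a log2 intensity of 4.92, the level under which 95% of a set of mostly dark probe sets fell, so that their folds are set against background.

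Among the lowered genes, PTGS2 fell by 3.20 (log2, SE 0.63; limma, Benjamini-Hochberg adjusted p = 0.0065) and FERMT1, an integrin activator of epithelial cells, fell by 3.09 (SE 0.31; adjusted p = 3.1e-04). FABP4, a fatty acid carrier of macrophages and adipocytes, changed by -2.97 (SE 0.10; limma, Benjamini-Hochberg adjusted p = 1.1e-05), and FABP5, its relative, by -2.68 (SE 0.59; adjusted p = 0.0112). FABP5 lost its call when the variance was modelled with a trend and robustly (limma, Benjamini-Hochberg adjusted p = 0.053; the range over all alternatives was 0.00143 to 0.053). IL6, an inflammatory cytokine gene, S100A12, a calcium-binding protein gene of phagocytes, and AVD, the gene of the biotin-binding protein avidin, changed by -2.62, -2.87 and -2.97. Lower values were also found for CMBL (-2.99), the glutathione transferase gene GSTA3 (-2.95), the proton pump subunit gene ATP6V0D2 (-2.85), the transglutaminase gene TGM4 (-2.85) and DMBT1, a scavenger protein of mucosal surfaces (-2.53). For IL6 and ATP6V0D2, 2 of 3 probe sets each were lower, and 0 opposite changes were called. Some of these genes varied within a group. All of the lowered genes named here but FABP4 were highest on control 2 among the control arrays and on SCA2 3 among the SCA2 arrays. PTGS2 had log2 intensities of 7.78, 7.50 and 9.68 on the SCA2 arrays, and FABP5 7.89, 7.46 and 9.74.

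**Figure D1:**
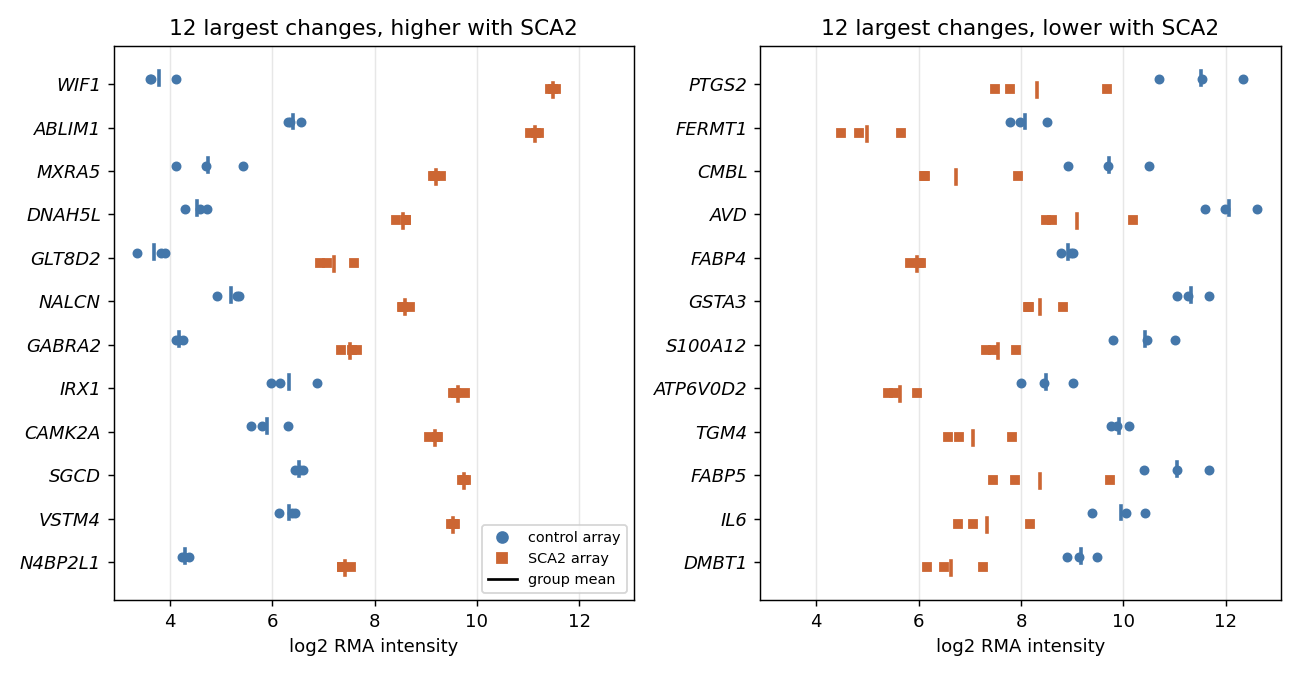
Log2 RMA intensity (x axis) of the 12 raised and the 12 lowered genes with the largest changes, with a circle for each of the 3 control arrays, a square for each of the 3 SCA2 arrays and a bar at each group mean. The groups do not overlap for any of these genes, and WIF1 moved from 3.79 to 11.48 while PTGS2 moved from 11.52 to 8.32.

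LY6E itself was not higher in the recovered cells. Its brightest probe set measured 10.05 ± 0.76 on the control arrays and 8.79 ± 0.48 on the SCA2 arrays (log2 intensity, n = 3 each), a change of -1.26 (SE 0.39; limma, Benjamini-Hochberg adjusted p = 0.0415), and the groups overlapped. The other 3 probe sets of LY6E lay between 3.97 and 4.51 in both groups, with changes of -0.19, -0.16 and -0.21 that did not pass the test. Whether these probe sets lie in the part of the transcript carried by the SCA2 construct is not known here, so they do not check the labels. The call was lost without control 2 (limma, Benjamini-Hochberg adjusted p = 0.104), control 3 (0.11), SCA2 1 (0.123) or SCA2 2 (0.113), and with a variance trend and robust fit (0.099), within a range over all alternatives of 0.00657 to 0.123.

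The list of B cell identity and receptor signalling genes was lower. Of its 34 measured members 31 fell and 0 rose, and the counts were 31 and 1 when adjusted over the list alone. PLCG2, a phospholipase downstream of the B cell receptor, changed by -1.53 (SE 0.08), CR2, a complement receptor, by -1.85 (SE 0.10), BTK, a kinase of receptor signalling, by -1.63 (SE 0.09) and PTPN6, a phosphatase that restrains it, by -1.66 (SE 0.10). CD79B, a chain of the receptor complex singled out after its values were seen, went from 12.75 ± 0.04 to 11.39 ± 0.13. CD40 (0.30), IRF8 (0.20) and PAX5 (-0.16) did not pass the test. The median member changed by -1.33, and limma's camera with Benjamini-Hochberg adjustment over the 25 lists gave an adjusted p = 6.8e-23, against an adjusted p = 0.265 with an estimated correlation. On these arrays the list of T and NK cell genes and the spiked hybridization controls were lower too, by a median of -0.82 and a mean of -1.43.

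Genes of antigen presentation by the major histocompatibility complex were lower as well. Of 17 measured members 12 fell and 1 rose, also when adjusted over the list alone, with a median of -0.50 (limma's camera, Benjamini-Hochberg adjusted p = 3.9e-06; adjusted p = 0.265 with an estimated correlation). DMA, a peptide loader of class II, changed by -1.41, CIITA, the activator of class II genes, by -1.89, the peptide transporter gene TAP2 by -1.28 and the class I gene BF2 by -1.57. The member that rose was the chaperone gene CALR (1.47). On the same arrays the lists of macrophages and dendritic cells, of B cells and of T and NK cells, whose cells carry such genes, had medians of -1.27, -1.33 and -0.82. Chromatin and lymphoid transcription factors had 21 of 41 members lower and 5 higher (22 and 8 adjusted over the list alone), a median of -0.26 and an adjusted p = 0.0032 in limma's camera with Benjamini-Hochberg adjustment (adjusted p = 0.265 with an estimated correlation). DNMT3A, a DNA methyltransferase, changed by -1.64, FLI1 by -1.51, MEF2D by -1.23 and ELF1 by -0.97.

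The lists for immunoglobulin diversification and for plasma cells were not called. In the first, 8 of 28 members rose and 7 fell (8 and 7 adjusted over the list alone), the median was -0.05 and the mean 0.10 (limma's camera, Benjamini-Hochberg adjusted p = 0.618). ID1, an inhibitor of basic helix-loop-helix factors, changed by 2.35, RAD52 by 1.2, ID3 by 0.77 and the translesion polymerase gene POLH by -1.21. In the plasma cell list 3 of 9 members rose and 4 fell, also adjusted over the list alone, with a median of 0.05 and a mean of -0.32 (limma's camera, Benjamini-Hochberg adjusted p = 0.526), and its median turned negative after quantile or cyclic loess normalization. CD38 changed by -2.27 and IRF4 by -1.28, while SDC1 and CREB3L2 each changed by 0.76.

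Markers of 5 other cell types, fixed as lists because bursal cells come from a whole organ and were washed off fibroblasts, were called, 4 of them lower and that for fibroblasts higher. In the T and NK cell list 20 of 29 members fell and 2 rose (21 and 2 adjusted over the list alone). CD3D and CD247, chains of the T cell receptor complex, changed by -1.54 and -1.67, TARP by -1.39 and the costimulatory receptor gene CD28 by -2.10, while LEF1 (1.11) and UBASH3A (0.65) were the members that rose (limma's camera, Benjamini-Hochberg adjusted p = 3.5e-08; adjusted p = 0.222 with an estimated correlation). In the macrophage and dendritic cell list 22 of 34 members fell and 1 rose (23 and 2 adjusted over the list alone), with a median of -1.27 (limma's camera, Benjamini-Hochberg adjusted p = 5.4e-05; adjusted p = 0.356 with an estimated correlation). The scavenger receptor gene CD36 changed by -2.01, the chemokine gene IL8L1 by -2.46 and the lysozyme gene LYG2 by -1.66, and C1S, a complement protease gene, was the member that rose (1.71). In the erythroid cell and thrombocyte list 11 of 18 members fell and 0 rose, also adjusted over the list alone, with a median of -0.50 (limma's camera, Benjamini-Hochberg adjusted p = 0.0105; adjusted p = 0.37 with an estimated correlation). CA2, a carbonic anhydrase gene, changed by -1.05, the clotting factor gene F13A1 by -1.42, the anion exchanger gene SLC4A1 by -0.99 and the alpha globin gene HBAD by -0.53. This call was lost without control 1 (limma's camera, Benjamini-Hochberg adjusted p = 0.0928) or control 3 (0.0673), within a range of 0.00104 to 0.0928 over all 16 alternatives with a preset correlation.

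In the epithelium list 12 of 29 members fell and 1 rose, also adjusted over the list alone, with a median of -0.82 (limma's camera, Benjamini-Hochberg adjusted p = 0.0042; adjusted p = 0.44 with an estimated correlation). PROM1 changed by -1.65, the transcription factor gene ELF3 by -1.47 and the protease gene TMPRSS2 by -0.81, and CLDN5, a claudin of endothelial junctions, was the member that rose (0.56). The mean of this list also differed within groups. Relative to the control mean it stood at -0.44, 0.43 and 0.00 on control 1, 2 and 3 and at -1.08, -1.19 and -0.46 on SCA2 1, 2 and 3. Without control 2 the median of the list was -0.543, and over all arrays left out in turn it lay between -1.03 and -0.543.

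The fibroblast and extracellular matrix list was split. Of its 65 measured members 33 rose and 13 fell (35 and 15 adjusted over the list alone), with a median of 0.36 (limma's camera, Benjamini-Hochberg adjusted p = 4.4e-05; adjusted p = 0.222 with an estimated correlation). The collagen genes COL6A2 and COL5A1 changed by 1.91 and 2.75, the matrix glycoprotein gene SPARC by 1.82, from 8.71 ± 0.05 to 10.53 ± 0.03, and the secreted Wnt modulator gene DKK3 by -1.54. The following were chosen after their values were seen. COL1A1, which encodes the main chain of type I collagen, went from 12.29 ± 0.18 to 13.32 ± 0.05. COL3A1 (0.08) did not pass the test, while POSTN (-1.62), IGFBP7 (-1.78) and FN1, the fibronectin gene (-0.29; limma, Benjamini-Hochberg adjusted p = 0.0355), fell. Collagen genes as a family, also chosen after the data were seen, were not called as a group, with 8 of 42 higher and 6 lower (median -0.04; limma's camera, Benjamini-Hochberg adjusted p = 0.432).

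**Figure D2:**
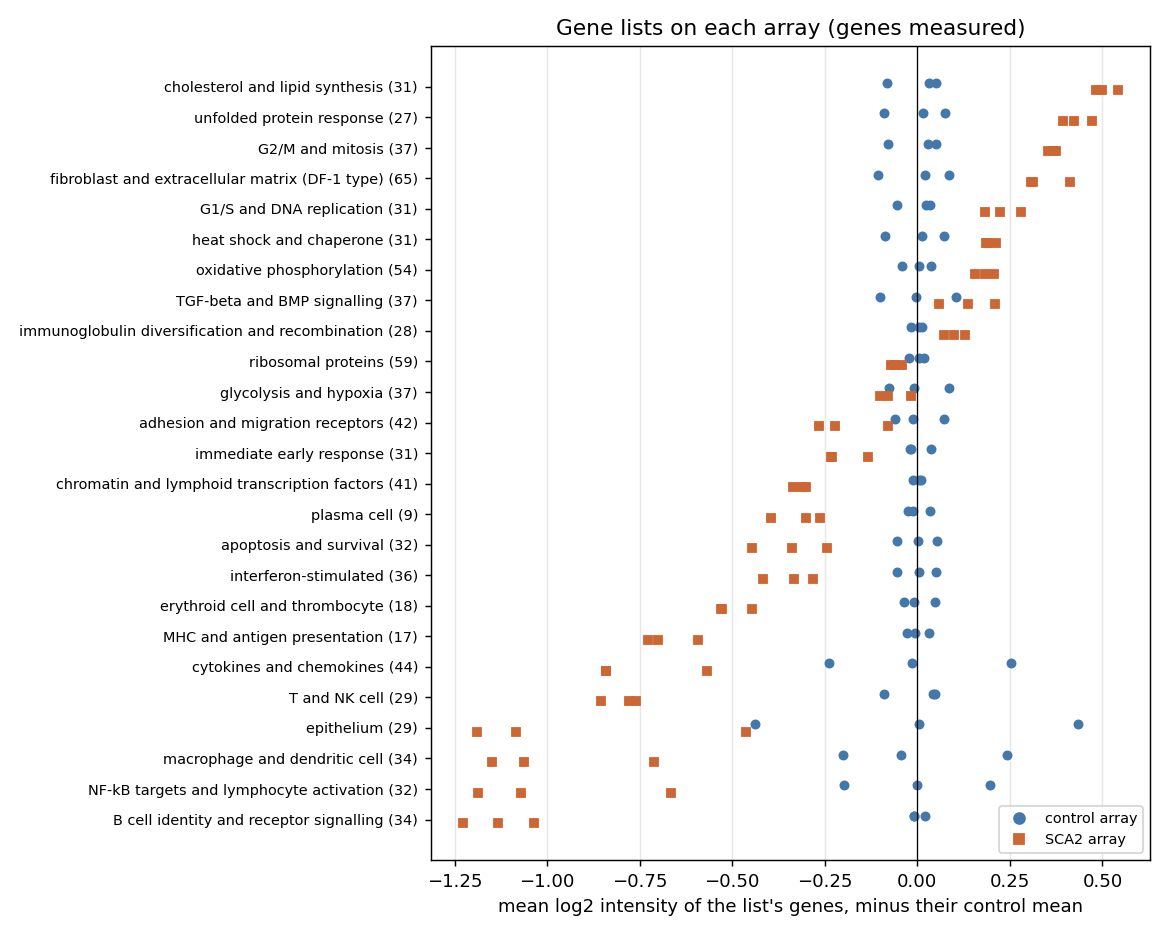
Mean log2 intensity of the genes of each list on each array, minus the mean of the control arrays (x axis), for the 25 gene lists (y axis, with the number of genes measured). Circles are the 3 control arrays and squares the 3 SCA2 arrays; B cell genes lay between -1.23 and -1.04 on the SCA2 arrays and fibroblast genes between 0.31 and 0.41.

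Genes of lymphocyte activation and inflammation were lower. Among targets of NF-kB, a transcription factor of immune activation, 20 of 32 members fell and 2 rose (21 and 3 adjusted over the list alone), with a median of -0.98 (limma's camera, Benjamini-Hochberg adjusted p = 4.7e-06; adjusted p = 0.356 with an estimated correlation). CCL20, a chemokine gene, changed by -1.78, NFKBIZ, an atypical inhibitor of the pathway, by -1.45, IRF1 by -1.24 and TRAF3 by -1.07. The list of cytokines and chemokines had 21 of 44 members lower and 4 higher (23 and 4 adjusted over the list alone), with a median of -0.43 (limma's camera, Benjamini-Hochberg adjusted p = 1.9e-04; adjusted p = 0.405 with an estimated correlation). IFNG, the gene of interferon gamma, changed by -2.02, IL18 by -1.19 and IL8L1 by -2.46. The cytokine list shared 14 members with other lists and the NF-kB list 11, so their calls are not independent. On the same arrays the macrophage and dendritic cell list and the epithelium list were lower, with medians of -1.27 and -0.82. The NF-kB list differed within groups as the epithelium list did, with means relative to the control mean of -0.20, 0.20 and 0.00 on control 1, 2 and 3 and of -1.07, -1.19 and -0.67 on SCA2 1, 2 and 3, and the cytokine list stood at -0.24, 0.25 and -0.01 on the control arrays and at -0.84, -0.84 and -0.57 on the SCA2 arrays.

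Interferon-stimulated genes had 18 of 36 members lower and 3 higher (18 and 5 adjusted over the list alone), with a median of -0.30 (limma's camera, Benjamini-Hochberg adjusted p = 0.0086; adjusted p = 0.265 with an estimated correlation). IFI27L2 changed by -1.13, IFI6 by -1.31 and DTX3L by -0.60. The members that rose were NMI (0.67), IRF9 (0.52) and TLR3 (0.40), the last with a control mean below the background mark of 4.92. In the list of apoptosis and survival 18 of 32 members fell and 7 rose (20 and 7 adjusted over the list alone), with a median of -0.39 (limma's camera, Benjamini-Hochberg adjusted p = 0.0106; adjusted p = 0.405 with an estimated correlation). The members with the smallest p acted in different ways, since BIRC2 and BCL2A1, inhibitors of cell death, changed by -0.998 and -1.47 while BMF, which promotes it, changed by -2.10, and PDCD4 by -1.17. The immediate early genes were not called, with 8 of 31 higher and 12 lower (9 and 14 adjusted over the list alone; median -0.13; limma's camera, Benjamini-Hochberg adjusted p = 0.378). RGS2, a regulator of G protein signalling, changed by 1.40, the kinase gene PIM3 by -1.41, and the growth-restraining genes BTG2 and BTG1 by -0.89 and -0.53. On these arrays the B cell list had a median of -1.33 and the macrophage and dendritic cell list of -1.27.

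Genes of cholesterol and lipid synthesis rose. Of 31 measured members 23 were higher and 1, the malic enzyme gene ME1 (-1.99), was lower (25 and 1 adjusted over the list alone), with a median of 0.57 (limma's camera, Benjamini-Hochberg adjusted p = 1.8e-04; adjusted p = 0.265 with an estimated correlation). The sterol enzyme genes SC5D, DHCR7 and NSDHL changed by 1.32 (SE 0.09), 1.63 (SE 0.12) and 1.25 (SE 0.11) and the fatty acid elongase gene ELOVL6 by 0.84 (SE 0.07). In the list of the unfolded protein response 16 of 27 members rose and 5 fell (17 and 5 adjusted over the list alone), with a median of 0.47 (limma's camera, Benjamini-Hochberg adjusted p = 0.0061; adjusted p = 0.405 with an estimated correlation). The endoplasmic reticulum chaperone genes SDF2L1, DNAJC3 and HYOU1 changed by 1.81, 1.02 and 1.23 and CHAC1, which degrades glutathione, by -1.37. On the same arrays the fibroblast list had a median of 0.36.

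Genes of G2/M and mitosis were higher for 22 of 37 members and lower for 3 (24 and 3 adjusted over the list alone), with a median of 0.38 (limma's camera, Benjamini-Hochberg adjusted p = 0.0058; adjusted p = 0.405 with an estimated correlation). The spindle genes PRC1 and KIF20A changed by 1.14 and 1.33, the centromere gene CENPI by 0.89 and CDC20, an activator of the anaphase-promoting complex, by 0.66, and KIF20A had another probe set called in the opposite direction. The members that fell were MKI67 (-0.42), NCAPG (-0.32) and SMC4 (-0.27). On the same arrays the fibroblast list had a median of 0.36, the B cell list of -1.33 and the hybridization controls a mean difference of -1.43. The list of G1/S and DNA replication had 15 of 31 members higher and 2 lower (15 and 3 adjusted over the list alone) and was not called (median 0.25; limma's camera, Benjamini-Hochberg adjusted p = 0.177). RRM1, a subunit of ribonucleotide reductase, changed by 0.99, the thymidylate synthase gene TYMS by 0.62, RFC3 by 0.73 and MCM5 by 0.48.

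The lists of oxidative phosphorylation, of heat shock, of glycolysis and of ribosomal proteins were not called. Oxidative phosphorylation had 25 of 54 members higher and 2 lower (25 and 3 adjusted over the list alone; median 0.17; limma's camera, Benjamini-Hochberg adjusted p = 0.0756), led by NDUFA1 (0.91), COX15 (0.59), NDUFS4 (0.69) and NDUFS8 (0.56). With a variance trend and robust fit it passed (limma's camera, Benjamini-Hochberg adjusted p = 0.0145), within a range of 0.0145 to 0.336 over the alternatives with a preset correlation, and the adjusted p = 0.44 with an estimated correlation. Heat shock and chaperone genes had 15 of 31 members higher and 3 lower (15 and 4 adjusted over the list alone; median 0.18; limma's camera, Benjamini-Hochberg adjusted p = 0.177), with HSPB1 at 1.31, BAG3 at 0.68, CHORDC1 at 0.55 and HSPB9 at -0.79. Glycolysis and hypoxia genes had 8 of 37 members higher and 9 lower (9 and 9 adjusted over the list alone; median 0.05, which turned negative after cyclic loess normalization, mean -0.07; limma's camera, Benjamini-Hochberg adjusted p = 0.831). Among them the glucose transporter gene SLC2A1 changed by 0.73 and P4HA2 by 0.75, while the angiogenic factor gene VEGFA changed by -1.08 and MXI1 by -0.86. Of 59 ribosomal protein genes 5 fell and 0 rose, and none passed when adjusted over the list alone (median -0.07; limma's camera, Benjamini-Hochberg adjusted p = 0.268). They were led by RPL12 (-0.34), RPS7 (-0.26), RPL7 (-0.24) and RPL29 (-0.25), of which RPS7, RPL7 and RPL29 lost their calls under at least 5 of 14 alternatives each.

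The list of TGF-beta and BMP signalling had 14 of 37 members higher and 8 lower (15 and 9 adjusted over the list alone; median 0.14; limma's camera, Benjamini-Hochberg adjusted p = 0.101). The ligand genes INHBB and TGFB3 changed by 1.35 and 0.96, LTBP1, which binds latent TGF-beta, by 0.78 and ID1, a target of BMP signalling, by 2.35. Adhesion and migration receptors had 13 of 42 members higher and 17 lower (13 and 19 adjusted over the list alone; median -0.21; limma's camera, Benjamini-Hochberg adjusted p = 0.687, with fry pointing up). The integrin genes ITGB5, ITGA3 and ITGA1 changed by 2.26, 1.13 and -0.74 and JAM2, a junctional adhesion molecule gene, by -1.19. In all, 15 of the 25 lists were called, 11 lower and 4 higher. Some lists share members, so these calls are not all separate results. With an estimated correlation 0 lists were called in limma's camera, 4 lists had an unadjusted p under 0.05, and fry, which asks whether the genes of a list move one way without comparing them with other genes, called 21.

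Control sequences added to the samples also differed. The 27 hybridization control probe sets, which report transcripts added just before hybridization, averaged 11 ± 0.37 on the control arrays and 9.57 ± 0.36 on the SCA2 arrays (log2 intensity, n = 3 each), a difference of -1.43, and 27 of the 27 were called lower by limma. The 36 probe sets for poly-A controls, which are usually added before labelling, averaged 11.07 ± 0.31 and 10.27 ± 0.09, a difference of -0.80, and 27 of them were called lower. Both differences stayed negative after quantile normalization, median centring and cyclic loess. Both kinds hold several probe sets for the same added transcript, so the counts called are not of independent readings. The 23 empty controls averaged 3.64 and 3.56, and 0 of them were called in either direction by limma. The log2 difference between the 3' and 5' probe sets of ACTB was 0.53 ± 0.39 on the control arrays and 0.09 ± 0.28 on the SCA2 arrays (two-sided exact permutation p = 0.2). For GAPDH it was 0.16 ± 0.05 and -0.06 ± 0.05 (exact permutation p = 0.1, the smallest that 3 arrays against 3 allow) and for EEF1A1 0.76 ± 0.34 and 0.58 ± 0.25 (exact permutation p = 0.5).

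**Figure D3:**
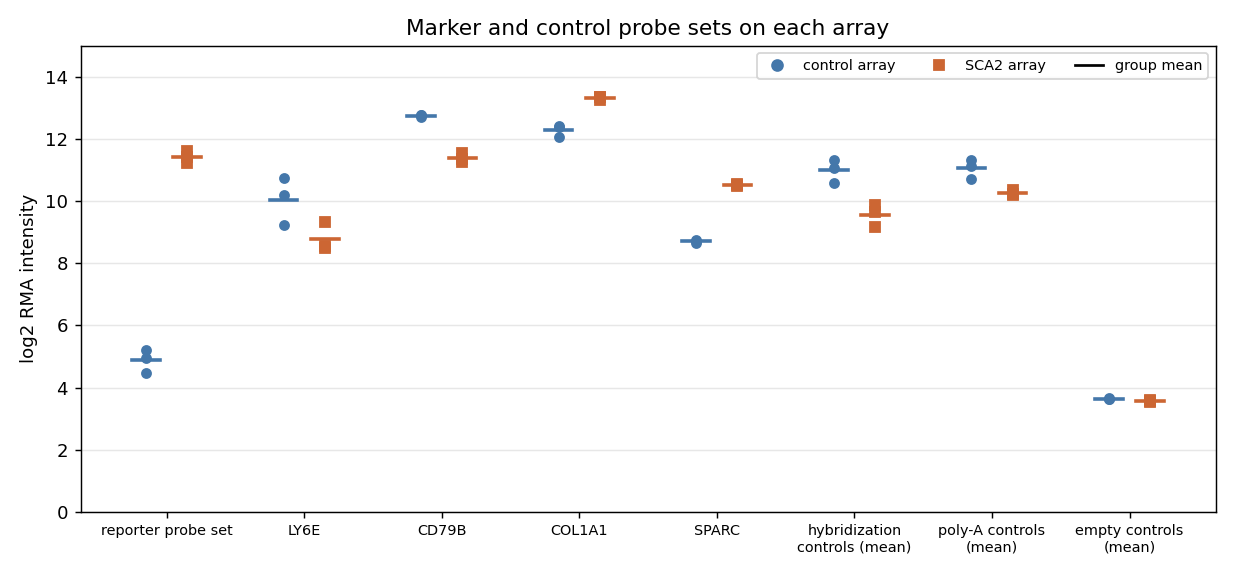
Log2 RMA intensity (y axis) of single probe sets and of the mean of each kind of control sequence (x axis), with a circle for each of the 3 control arrays, a square for each of the 3 SCA2 arrays and a bar at each group mean. CD79B and both kinds of added control were lower on the SCA2 arrays, COL1A1 and SPARC were higher, and a reporter probe set went from 4.87 to 11.42.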

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

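The tests of cell mixture, of the reporter and, through cyclic loess, of an intensity trend were chosen only after the results were seen.

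A probe set for a reporter sequence, which is no chicken gene and stands in no gene list, was bright on the SCA2 arrays alone and measured 4.87 ± 0.37 on the control arrays and 11.42 ± 0.19 on the SCA2 arrays (log2 intensity, n = 3 each), a change of 6.55 (SE 0.19; limma, Benjamini-Hochberg adjusted p = 1.02e-05) and the second largest rise of all probe sets after WIF1. Both had control means below the background mark of 4.92, so these sizes and ranks are set against background. It was singled out because it is a signal outside the chicken genes that stands above the control arrays, and the other 56 reporter probe sets changed by at most 0.48 either way. RNA of a transfected monolayer in the harvest stays open: on the SCA2 arrays the fibroblast gene COL1A1 lay at or above the 99.6th percentile of all probe sets and FN1 and COL1A2 at about the 96.0th or higher, but COL3A1, COL5A1, SPARC and TAGLN lay between 91.9 and 94.6 and ACTA2 between 15.3 and 17.2. COL1A1 also lay between 98.2 and 98.9 on the control arrays and FN1 between 99.6 and 99.7. RNA of these fibroblast genes was thus abundant in both groups, and its level does not set the SCA2 arrays apart. Whether bursal cells express these genes and what each construct carries are not known here. Cross-hybridization to a chicken transcript is open too, since no probe sequences were compared. Only 1 other probe set, that of WIF1, rose by 6 or more, which does not show what the reporter probe set binds.

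Lists of blood cell genes were lower and the fibroblast list mostly higher, which a larger share of monolayer RNA on the SCA2 arrays could give, although the cells were recovered by washing them off an adherent layer. Such a share would lower all blood cell genes alike only if the monolayer expressed none of them and every probe set followed its RNA equally. Neither was tested. The median of erythroid and thrombocyte genes above background lay 0.86 (log2, bootstrap 95% interval 0.42 to 1.17) above that of the B cell genes. This argues only against an equal fall of these lists, not against a mixture. The differences for T and NK cells (0.15, -0.24 to 0.66) and for macrophages and dendritic cells (0.0875, -0.36 to 0.50) include 0 and are too wide to decide. The bootstrap drew genes as if independent, and not arrays. With both monolayers alike, genes expressed by the monolayer alone would also rise together, yet 22.8% of the 57 members above background fell, among them POSTN and FN1. The bursal cells come from a whole organ, and whether they express these genes too is not known here, so the falls do not decide. Left open are monolayers that differ from each other, a mixture for part or all of the change and a response of the bursal cells to SCA2. Of the 65 fibroblast genes 57 were above background on the control arrays, and 2 stand in another list.

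The large number of calls, 13557 probe sets, came together with lower added controls on the SCA2 arrays (hybridization controls by -1.43), which a difference between the hybridizations could give. A trend with intensity is argued against as the whole cause. After cyclic loess normalization 12810 probe sets were called, 11720 of them shared, and the median of the B cell list was -1.44. The hybridization controls differed by -1.53 after it, so cyclic loess does not address what lowered them. The 3 against 3 arrays make 10 splits, too few for a share under 0.05: 1 split, the real one, gave 13557 calls and the highest other gave 0 (limma; 240 to 1717 at an unadjusted p under 0.05). For gene lists the real split gave 15 calls, again the most in 1 of 10, and the highest other gave 14; every other split sets 2 arrays of one group with 1 of the other and so keeps part of the real difference, and its counts do not show what no change would give. A batch of hybridization or labelling that affects some probes more than others cannot be told apart from the monolayer, because no batch is given, and an effect of SCA2 stays among the open explanations.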

How the results depend on the processing

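Cyclic loess normalization and the estimated correlation for the lists of other cell types were chosen after seeing the data. Counts of probe sets stayed within 1.5 times under each normalization, filter, variance model and set of array weights and without moderation (5400 higher, 4723 lower). Stricter thresholds left fewer, with 3702 lower (and 4679 higher) at an adjusted p under 0.01 and 1667 higher and 1325 lower at 2-fold or more. Leaving out 1 array gave 5378 to 6748 higher and 4497 to 6335 lower probe sets, 14 to 15 called lists, 4 to 5 of them of other cell types, a first component of 75.2% to 83.4% and an LY6E change of -1.67 to -0.92. LY6E lost its call without control 2, control 3, SCA2 1 or SCA2 2 and with a variance trend and robust fit (-1.26; limma, Benjamini-Hochberg adjusted p = 0.099); the cause was not tested. With an estimated correlation, limma's camera called 0 lists and 0 of the 5 lists of other cell types, while fry called 21. At an unadjusted p under 0.05, camera with an estimated correlation gave 4 of 25 lists. The estimated correlation was -0.006 for the fibroblast list and -0.018 for the chromatin list, below the preset 0.01. A higher correlation between genes therefore does not explain why these lists lost their calls. What else did was not tested, nor was the cause for the other lists. The medians of uncalled lists reversed for plasma cell genes, to -0.0188 after quantile and -0.0476 after cyclic loess normalization, and for glycolysis and hypoxia, to -0.0279 after cyclic loess; the cause was not tested. Other list medians kept their direction in all 16 alternatives, with 2 of 400 values losing a call (erythroid and thrombocyte genes without control 1 or control 3) and 1 gaining it (oxidative phosphorylation). Of 1692 values for 121 named probe sets, the reporter included, 1673 kept direction and call, 19 lost the call (FABP5, RPS7, RPL7 and RPL29) and 0 reversed. Some medians of called lists moved by over 1.5 times with no call lost, such as those of cytokines (-1.22), T and NK cells (-1.27), antigen presentation (-0.85) and fibroblast genes (0.70) among probe sets above the median, and that of epithelium (-0.543) without control 2. With 1 array left out, medians of uncalled lists ranged from 0.0845 (without control 1) to 0.215 for TGF-beta and BMP signalling, -0.137 to -0.0507 (without SCA2 1) for immediate early genes, -0.079 to -0.0266 for immunoglobulin diversification, 0.0171 to 0.0761 for plasma cell genes and 0.00166 to 0.0802 for glycolysis and hypoxia. The median change of all probe sets lay between -0.06 and 0.04 and the share of higher calls between 49.1% and 56.5%. Probe sets near background limit what a small change can show.

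With the replicate number as a replicate block, 7618 probe sets were higher, 6913 lower (12928 shared with the reported calls) and 15 lists were called, 5 of them of other cell types; LY6E kept its call at -1.26 (limma, Benjamini-Hochberg adjusted p = 0.0223). Deviations from the group means correlated at 0.41, 0.12 and 0.04 between arrays of the same number, and 0.41, for control 1 and SCA2 1, was the highest of any pair across groups. Control 2 correlated best with SCA2 3 (0.33), so whether the numbers pair the arrays is not settled.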

Other observations

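The 35 gene families below were formed by symbol and tested after the data were seen, in addition to the lists. HOX genes, taken by symbol and nearly all of them transcription factors that mark position along the body axis, were the 1 family called by limma's camera. Of 30 measured members 13 rose and 1 fell, led by HOXA7 (log2 change 2.44, SE 0.09), HOXC9 (1.87, SE 0.08), HOXB3 (1.70, SE 0.10) and HOXB4 (1.48, SE 0.09), with the antisense RNA HOXA10-AS (1.16) among those that rose and a median of 0.11 (limma's camera, Benjamini-Hochberg adjusted p = 0.0114; adjusted p = 0.696 with an estimated correlation). On the same arrays the fibroblast and extracellular matrix list had 33 of 65 members higher and a median of 0.36, and the macrophage and dendritic cell list had a median of -1.27. Of 8 Toll-like receptors, sensors of microbial products, 6 fell and 1 rose, with TLR15 at -1.84, TLR7 at -1.78, TLR1A at -1.61 and TLR2A at -1.57 (median -1.16; limma's camera, Benjamini-Hochberg adjusted p = 0.137). Of 10 chemokine receptors 6 fell and 1 rose, among them CXCR4, the receptor for CXCL12 (-1.52; limma's camera for the family, Benjamini-Hochberg adjusted p = 0.175), and after cyclic loess normalization 3 fell. The median of each of these 3 families kept its sign after quantile normalization, median centring and cyclic loess, and that of the HOX genes went to 0.18 after quantile normalization and 0.20 after cyclic loess.

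Other families had more members higher than lower without passing the family test. Of 67 genes for mitochondrial ribosomal proteins 28 rose and 5 fell, among them MRPL10 (0.94) and MRPS34 (0.73) (limma's camera, Benjamini-Hochberg adjusted p = 0.137). Of 17 tubulins 10 rose and 1 fell, with TUBA5 at 0.95 and TUBB2B at 0.81 (limma's camera, Benjamini-Hochberg adjusted p = 0.161), and of 33 kinesins 15 rose and 3 fell, with KIF26A at 1.60 (limma's camera, Benjamini-Hochberg adjusted p = 0.137). These medians kept their sign under the same 3 scalings, with 20 mitochondrial ribosomal protein genes higher after cyclic loess normalization.

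There were 22 probe sets with 1 gene symbol that differed by 4-fold or more and did not pass limma's test, and 22 of them were lower on the SCA2 arrays. In 22 of 22 the highest value was on control 2. They included the secreted protease genes MMP1, MMP9, MMP10 and MMP13, the protease inhibitor gene SERPINB2 and the keratin gene KRT5. PLAU, the urokinase gene, measured 9.87, 13.09 and 12.08 on control 1, 2 and 3 and 8.04, 6.29 and 11.13 on SCA2 1, 2 and 3 (log2 intensity; limma, Benjamini-Hochberg adjusted p = 0.0928).

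The 689 probe sets named after sequence records were mostly dark, with a median log2 intensity of 3.09 against 5.77 for the chicken probe sets. Of these 2 were called higher and 30 lower (4.64%), and the largest changes were 0.41 and -0.64.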
